A study of Pseudomonas protegens with 9 samples.

How the data were processed

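RNA of *Pseudomonas protegens* CHA0 was measured after a 1 h treatment with WT (Col-0) root exudates, glutamine or sgn3 myb36 root exudates, with 3 libraries in each of 3 groups. Per the labels' protocols, total RNA was treated with DNase, depleted of ribosomal RNA with a kit that uses RNase H and probes described as directed against plant rRNA, and made into libraries with a kit that keeps strand. The authors deposited raw counts per gene, one column per library, as whole numbers. The submitters' processing notes name Trimmomatic 0.32, STAR 2.7.9a and DESeq2 1.38.0, with no roles. The counting program, its strand setting, its treatment of reads that map to several places, the genome build and the annotation are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes are therefore uncertain, and the tags could not be checked for them, since no genome was used here.

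The table has 6198 rows: 6120 with a locus tag, 15 named as rRNA and 63 named as tRNA. The tags rise in steps of 10, and tags 1 step apart were taken as neighbours. Gene names are not paired with the tags, so 27 gene lists of metabolism, transport, motility, stress, secretion and regulation, and 10 genes that were to be named by symbol, matched 0 rows and were not tested. The planned test over gene lists, with its alternatives, could not be run for the same reason. The tRNA list matched 63 rows and was tested in the fit that kept these rows, where 28 had enough counts. The pattern written for the rRNA list missed the row names, which end in a letter; the 15 rows were recognised by their names and left out with the tRNA rows before library sizes were summed. Ribosomal RNA rows held 0.00123% to 0.0318% of the counts of a library, with group means of 0.0151% ± 0.0145 in WT exudate, 0.00508% ± 0.00337 in glutamine and 0.00291% ± 0.00178 in mutant exudate (SD, n = 3 each). Transfer RNA rows held 0.0158% to 0.0395%.

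Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, one quasi-likelihood fit of all 9 libraries with a mean per group, and a two-sided test per contrast with Benjamini-Hochberg adjustment at 0.05. The filter left 5977 genes. TMM factors ran from 0.886 to 1.08. CPM values are counts scaled by the TMM-adjusted library size, and principal components were computed on log2 CPM with a prior count of 2. Genes are named from those with the largest log2 fold changes in each direction, 10 per direction, among genes that passed the test, with a mean of at least 10 CPM and no overlap between the groups; since names are not paired with tags, at most 2 tags per direction are printed for a comparison. The tRNA list was tested with camera in limma 3.58.1, with an inter-gene correlation fixed at 0.01 and again with an estimated one. These choices were made before the data were examined, except the limit of 2 printed tags per direction. Tags printed for the first comparison were followed in the second, whatever their rank there. The count of runs of at least 3 neighbouring tags, the share of counts and the intervals of mutant exudate minus glutamine were added afterwards.

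Depth ran from 3677187 to 6995981 counts per library. A count of 0, with a floor of 3 counts, corresponds to between 0.429 and 0.816 CPM; this covers counting error only. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 6.93 to 90.3 over the pairs within groups, so none were taken for the same library. The procedure was tested on simulated counts for 5977 genes, with changes placed only in genes of at least 10 CPM. For glutamine minus WT exudate it recovered 29.9% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold, with 9.03% of the calls false. For mutant exudate minus WT exudate the values were 28.4%, 83.6% and 100%, with 6.62% false. For mutant exudate minus glutamine they were 35.8%, 91.0% and 100%, with 5.63% false. Intervals of 95% covered the true value for 95.2%, 95.8% and 95.5% of genes. Each gene was drawn independently, with the dispersion fitted to these data, so coverage near 95% was likely from the start. The simulated counts held no variation that moves many genes together, and all these values hold only for such counts.

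Comparisons that share the WT exudate libraries were set against 100 simulations of unchanged groups, with each gene drawn independently. Alternatives were DESeq2 size factors, upper-quartile scaling and library totals in the same fit, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts, a fit of the 6 libraries compared, rRNA and tRNA rows kept, the replicate number as a block, and leaving out each library. Leaving out the library of each group with the highest score on an axis of within-group variation, leaving out the one with the lowest score, thinning every library to the lowest total, and TMM without genes above 0.1% of counts were added after seeing the data.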

Results

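The bacterium studied was *Pseudomonas protegens* CHA0, a soil strain that colonises plant roots and protects them from fungal disease. Cells were treated for 1 h with root exudates of wild-type (WT, accession Col-0) *Arabidopsis thaliana*, with glutamine, or with root exudates of the sgn3 myb36 double mutant. MYB36 is a transcription factor that drives formation of the Casparian strip, the barrier of the root endodermis, and SGN3 is a receptor kinase needed to seal it. Total RNA was depleted of ribosomal RNA and sequenced from 3 libraries per group, 9 in all. Total counts ran from 3677187 to 5079313 in the WT exudate libraries, from 4741795 to 5667525 in the glutamine libraries, and from 5309705 to 6995981 in the mutant exudate libraries. Genes are identified by locus tag only: the deposited table does not pair the tags with gene names, so a few tags are given with their values and the rest are described as groups. There was no untreated group, so each value is relative to another treatment, and "higher" and "lower" name a difference between treatments. The labels do not say whether the 3 libraries of a group came from separate cultures; p-values then measure only the spread between these libraries, which may be technical.

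The WT exudate libraries stood apart from the other 6. The first principal component, with 59.5% of the variance, separated them from both the glutamine and the mutant exudate libraries, and the second, with 14.2%, spread libraries within each group. Spearman correlations of CPM across genes were 0.936 to 0.949 between WT exudate and glutamine libraries and 0.928 to 0.947 between WT exudate and mutant exudate libraries. Between glutamine and mutant exudate libraries they were 0.979 to 0.988. Within groups they were 0.979 to 0.985 for WT exudate, 0.987 to 0.992 for glutamine and 0.974 to 0.991 for mutant exudate, where the pairs with replicate 3 gave 0.974 and 0.975.

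**Figure D1:**
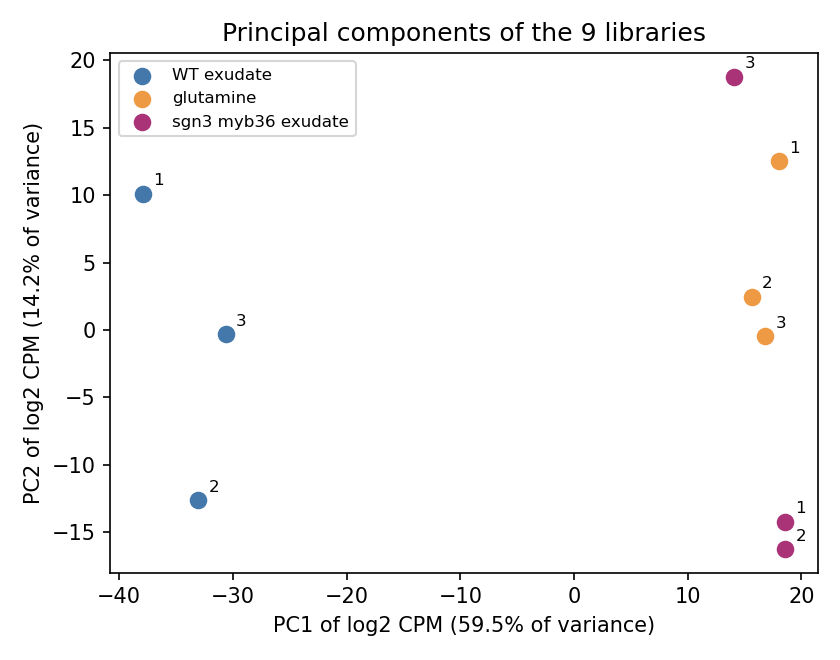
Principal components of log2 CPM, with PC1 on the x axis and PC2 on the y axis. Each point is a library, coloured by group and numbered by replicate; the WT exudate libraries lie apart on PC1 (59.5% of the variance), and libraries of each group are spread along PC2 (14.2%).

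The first comparison asked how the response to glutamine alone differed from the response to WT exudates. Expression differed in 1721 of 5977 genes tested (28.8%), of which 799 were higher and 922 lower in glutamine. The largest differences were all towards higher expression: 47 genes were 8-fold or more higher and 0 were 8-fold or more lower (edgeR). PFLCHA0_c02770 had the largest difference, from 19.3 ± 6.63 CPM in WT exudate to 1725 ± 431 CPM in glutamine (SD, n = 3 each), a log2 fold change of 6.46 (SE 0.23; edgeR adjusted p = 8.61e-09). PFLCHA0_c42170 followed, with 11.4 ± 1.27 CPM in WT exudate and 900.2 ± 48.4 CPM in glutamine, a log2 fold change of 6.31 (SE 0.16; edgeR adjusted p = 3.22e-10). In the other direction PFLCHA0_c21440 had 68.9 ± 19.1 CPM in WT exudate and 9.97 ± 1.49 CPM in glutamine, a log2 fold change of -2.77 (SE 0.25; edgeR adjusted p = 7.37e-06). PFLCHA0_c04080, among the more abundant transcripts, had 7952 ± 1180 CPM in WT exudate and 1273 ± 55 CPM in glutamine, a log2 fold change of -2.64 (SE 0.15; edgeR adjusted p = 1.59e-07). These 4 tags were named only if the 3 libraries of one group did not overlap those of the other. Over all genes tested 2631 (44.0%) did not overlap, where 10% would be expected by chance.

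The 10 genes with the largest increases were 47.5-fold to 88.3-fold higher in glutamine, and the 10 with the largest decreases were 4.32-fold to 6.84-fold lower. Of 380 genes that differed 2-fold or more, 201 were higher and 179 lower. Many of these were neighbours: 109 of the 380 lay in 25 runs of at least 3 consecutive tags that differed in the same direction, 17 runs higher and 8 lower. When the same genes were placed at random over the tags, 10000 shuffles gave a median of 0 genes in such runs and at most 15 (permutation p = 0.0001, the smallest these shuffles can give). The count of runs was chosen after the data were seen. The run that holds PFLCHA0_c02770 had 4 tags, with log2 fold changes from 4.96 to 6.46, and the longest run, all higher, had 10 tags from 1.55 to 6.03. The longest lower run had 4 tags. Of 28 transfer RNA (tRNA) rows with enough counts, 0 were higher and 2 lower over all genes tested, 2 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (edgeR), with a camera p of 0.651 for the list, and p = 0.886 with an estimated correlation. With 2 libraries per group, after leaving out WT exudate replicate 2, glutamine replicate 3 and mutant exudate replicate 2 (chosen after the data were seen), 359 genes were higher and 338 lower in glutamine, and 367 passed the test and differed 2-fold or more.

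The second comparison asked how exudates of the barrier mutant differed from WT exudates in their effect on the bacteria. Expression differed in 1897 of 5977 genes (31.7%), with 916 higher and 981 lower in mutant exudate. PFLCHA0_c02770 was again the tag with the largest difference, at 1796 ± 63.8 CPM in mutant exudate (SD, n = 3) against 19.3 ± 6.63 CPM in WT exudate, a log2 fold change of 6.52 (SE 0.23; edgeR adjusted p = 8.73e-09). PFLCHA0_c42170 had 841 ± 153 CPM in mutant exudate, a log2 fold change of 6.21 (SE 0.16; edgeR adjusted p = 4.4e-10). PFLCHA0_c21440 had 11.1 ± 3.09 CPM, a log2 fold change of -2.65 (SE 0.24; edgeR adjusted p = 9.76e-06). By contrast PFLCHA0_c04080 had 7580 ± 415 CPM in mutant exudate, and its log2 fold change against WT exudate was -0.07 (edgeR adjusted p = 0.76).

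The 10 largest increases in mutant exudate were 40.2-fold to 91.9-fold and the 10 largest decreases 3.67-fold to 6.28-fold. Of 410 genes that differed 2-fold or more, 217 were higher and 193 lower, and 43 were 8-fold or more higher against 0 lower (edgeR). Of the 410, 113 lay in 28 runs of consecutive tags, 17 higher and 11 lower (permutation p = 0.0001, the smallest that 10000 shuffles can give; at most 13 genes in a shuffle). The longest run, all higher, again had 10 tags. In the run of 4 tags that holds PFLCHA0_c02770 the log2 fold changes were 4.79 to 6.52. Of the 28 tRNA rows, 1 was higher and 2 lower, 5 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (edgeR), with a camera p of 0.662 and p = 0.890 with an estimated correlation. Without the same 3 libraries 364 genes were higher and 334 lower in mutant exudate, and 362 passed the test and differed 2-fold or more. Both comparisons with WT exudate rest on the same 3 WT exudate libraries.

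The responses to glutamine and to mutant exudate, both set against WT exudate, were then compared gene by gene. Of the genes tested, 684 were higher and 770 lower in both, 2 were called in opposite directions, 265 were called for glutamine only and 441 for mutant exudate only. Of those called in one comparison only, 5 differed between mutant exudate and glutamine themselves, so most of these 1-sided calls are not shown to be specific to either treatment. Without WT exudate replicate 2, glutamine replicate 3 and mutant exudate replicate 2, 295 genes were higher and 258 lower in both. Independent lists of the sizes found with all 9 libraries would share 122 higher and 151 lower genes, and simulations of unchanged groups against shared controls gave 0 to 2 shared calls. Across genes the 2 sets of log2 fold changes had a Pearson correlation of 0.935, where 100 simulations with no effect gave a median of 0.519 from the shared WT exudate libraries alone. Their covariance was 0.426 against a simulated median of 0.0299, a difference of 0.396. The sign was the same for 86.4% of genes, against 67.1% in the simulations. The WT exudate libraries were not split between the 2 comparisons, so part of the overlap may come from sharing them. In these values genes are not independent replicates.

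The 169 genes that were 2-fold or more higher in both comparisons took 2.14% ± 0.149 of the counts in WT exudate libraries, 10.6% ± 0.264 in glutamine libraries and 10.5% ± 1.05 in mutant exudate libraries (SD, n = 3 each). The 131 genes that were 2-fold or more lower in both took 10.9% ± 0.420, 4.41% ± 0.215 and 4.35% ± 0.0674. Both sets were chosen on these libraries, so their direction is not independent evidence.

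**Figure D2:**
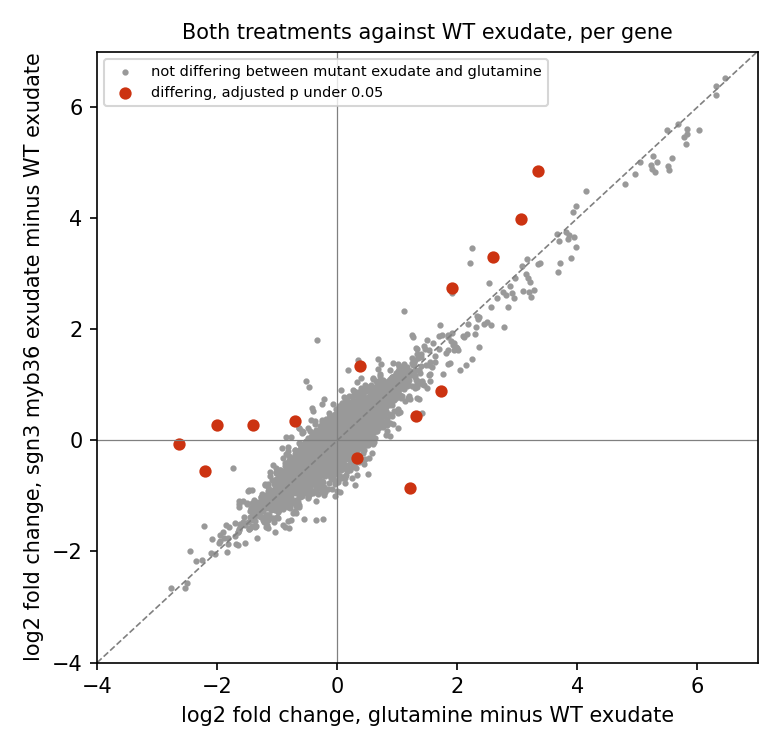
Log2 fold change of each tested gene in glutamine (x axis) and in sgn3 myb36 exudate (y axis), both against WT exudate; the dashed line marks equal changes. Red points are the 14 genes that differed between mutant exudate and glutamine (edgeR adjusted p under 0.05), and most other genes lie along the line (correlation across genes 0.935).

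The third comparison set mutant exudate directly against glutamine. In the edgeR fit of all 9 libraries 14 of 5977 genes differed, 10 higher and 4 lower in mutant exudate; 378 had an unadjusted p under 0.05, where 298.85 would be expected by chance. The largest difference was PFLCHA0_c04080, which was 7580 ± 415 CPM in mutant exudate and 1273 ± 55 CPM in glutamine (SD, n = 3 each), a log2 fold change of 2.57 (SE 0.15; edgeR adjusted p = 9.55e-06). It belonged to a run of 4 consecutive tags that were all higher in mutant exudate, with log2 fold changes from 1.06 to 2.57. The median log2 fold change of these 4 tags was 0.28 between mutant exudate and WT exudate and -1.70 between glutamine and WT exudate. The largest difference in the other direction was PFLCHA0_c31290, at 86.0 ± 9.06 CPM in mutant exudate, 359 ± 94.2 CPM in glutamine and 155 ± 19.8 CPM in WT exudate. Its log2 fold change was -2.06 between mutant exudate and glutamine (SE 0.18; edgeR adjusted p = 0.000291), and it was 1 of the 2 genes called in opposite directions against WT exudate. Of the 28 tRNA rows 0 differed (edgeR, over all genes and when adjusted over the list alone) and 2 had an unadjusted p under 0.05, with a camera p of 0.916 and p = 0.973 with an estimated correlation.

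The interval of the difference between mutant exudate and glutamine was then examined. Of the 380 genes that differed 2-fold or more between glutamine and WT exudate, 337 (88.7%) had a 95% confidence interval of mutant exudate minus glutamine that lay within 2-fold. Over the 490 genes that differed 2-fold or more in either comparison with WT exudate, 418 (85.3%) had such an interval and 12 were called different. Over all 5977 genes tested, most of which differed little from WT exudate in either treatment, the share was 89.8%. In simulations of this comparison, genes with a true 2-fold difference were called in 91.0% of cases and those with a 1.5-fold difference in 35.8%. Smaller differences were thus often not detectable with 3 libraries per group. The simulation gave 160 calls, against 14 in the data. A threshold adjusted over fewer calls is stricter, so both shares are likely too high for these data.

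The count of 14 depended on the test and on single libraries. It was 42 with the DESeq2 Wald test (24 higher, 18 lower), which gave an adjusted p for only 3389 genes, against 5977 in the edgeR fit. With the replicate number as a block the count was 7 (6 higher, 1 lower). In a fit of only the 6 libraries compared it was 6 (5 higher, 1 lower). It was 6 without WT exudate replicate 2, 6 without glutamine replicate 1, 5 without glutamine replicate 2, 8 without glutamine replicate 3, 5 without mutant exudate replicate 1, 7 without mutant exudate replicate 2 and 46 without mutant exudate replicate 3, where 14 genes were higher and 32 lower. Without WT exudate replicate 1 it was 11, with 2 lower, and without WT exudate replicate 3 it was 19, with 8 lower. PFLCHA0_c04080 and PFLCHA0_c31290 passed the threshold in each of these fits. The libraries of each group spread along 1 axis of variation, on which WT exudate replicates 1 and 2 lay about equally far on opposite sides of their group mean (scores of 11.4 and -11.6). Leaving out the library of each group with the highest score (WT exudate replicate 1, glutamine replicate 1 and mutant exudate replicate 3) gave 23 higher and 101 lower genes. Leaving out the one with the lowest score (WT exudate replicate 2, glutamine replicate 3 and mutant exudate replicate 2) gave 3 higher and 0 lower genes (edgeR; 132 genes had an unadjusted p under 0.05), and PFLCHA0_c31290 no longer passed (log2 fold change -2.03, edgeR adjusted p = 0.0571). Both choices were made after the data were seen. Leaving out the highest scores kept pairs with a chi-square per degree of freedom of 22.2 in WT exudate, 6.93 in glutamine and 9.76 in mutant exudate. Leaving out the lowest scores kept pairs with 33.4, 17.4 and 90.3. The larger number of calls thus came with replicates that were closer to each other, in the comparisons with WT exudate as well.

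**Figure D3:**
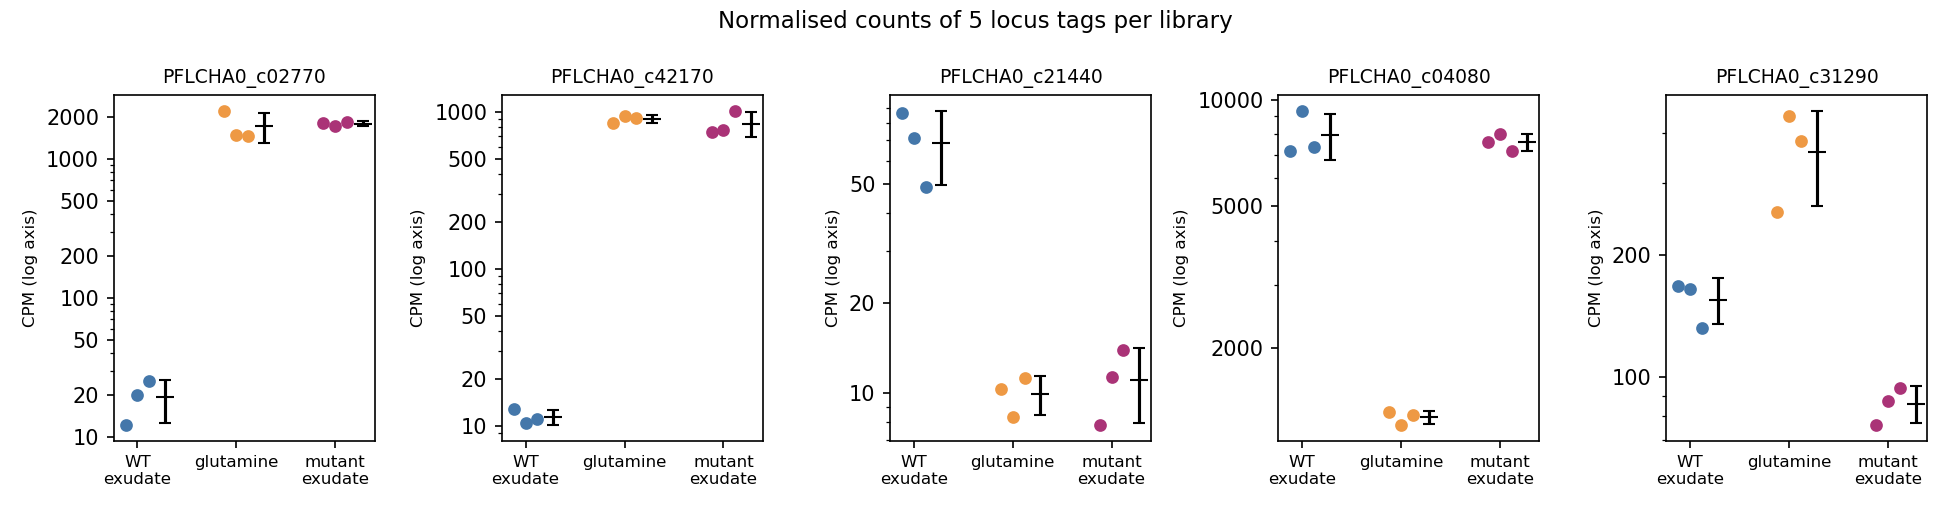
Normalised counts (CPM, log axis) of 5 locus tags. Coloured points are libraries and the black mark and bar give the mean and SD of each group (n = 3); PFLCHA0_c02770, PFLCHA0_c42170 and PFLCHA0_c21440 did not pass the test between glutamine and mutant exudate, whereas PFLCHA0_c04080 was at 7952 CPM in WT exudate and 7580 CPM in mutant exudate but 1273 CPM in glutamine, and PFLCHA0_c31290 was at 359 CPM in glutamine and 86.0 CPM in mutant exudate.

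**Figure D4:**
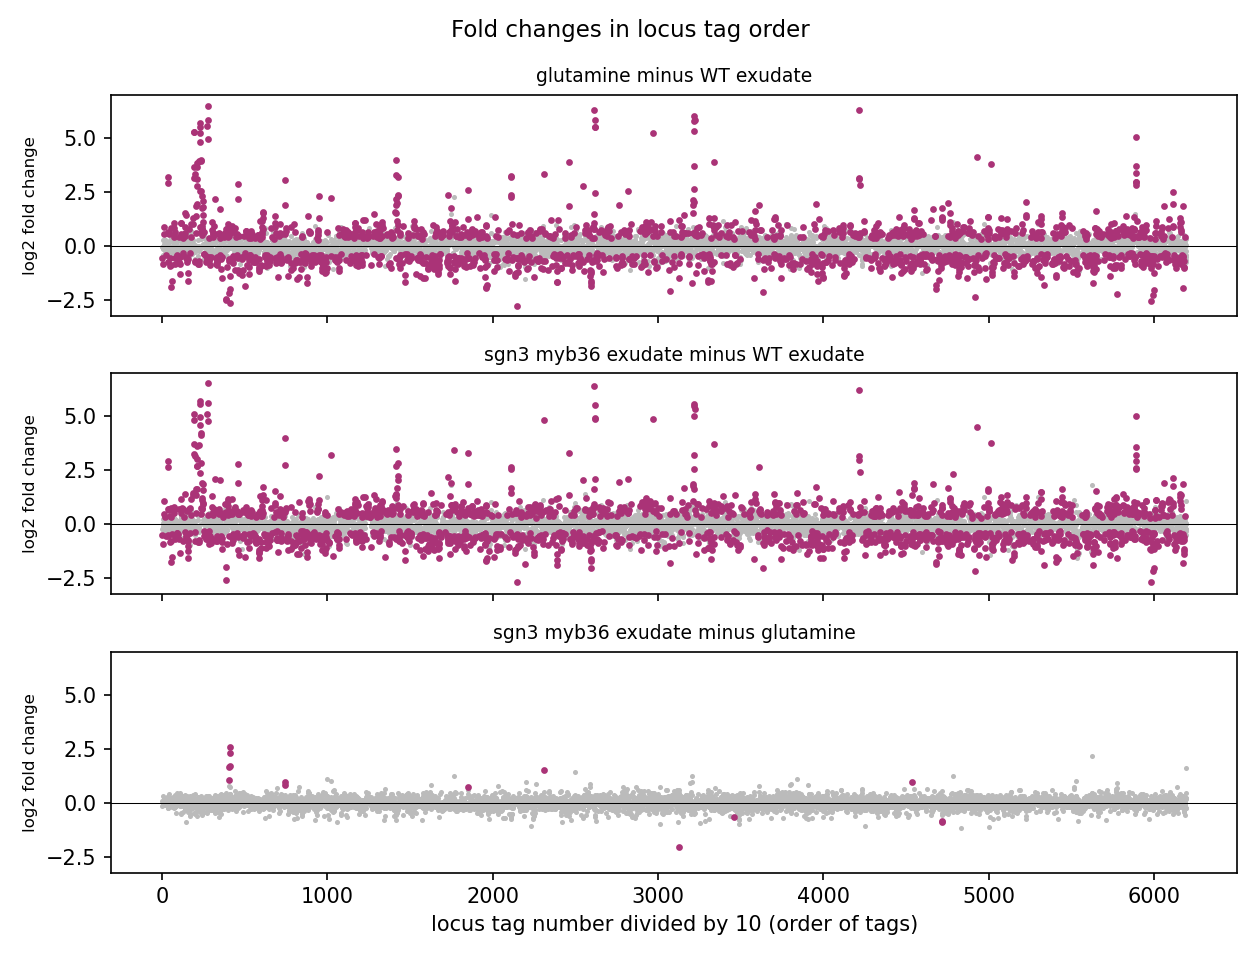
Log2 fold changes of the 3 comparisons (y axis) in the order of the locus tags (x axis). Purple points passed an edgeR adjusted p of 0.05 and grey points did not; 1721, 1897 and 14 genes passed, and the largest increases against WT exudate stand in narrow columns of neighbouring tags at the same places in the upper and middle panels.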

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

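Leaving out the highest-scoring or the lowest-scoring library of each group on the within-group axis, thinning, TMM without the most abundant genes, and the alternatives for intervals and runs were chosen after seeing the data. For genes shared by both comparisons, DESeq2 size factors, the stricter filter, the replicate block and leaving out single libraries were planned and the rest were not; the remaining alternatives were planned. Without the lowest-scoring libraries, calls fell to 359 higher and 338 lower for glutamine, 364 higher and 334 lower for mutant exudate, and 295 higher and 258 lower in both; no called gene changed sign. Library number alone does not account for the fall. Leaving out the highest-scoring libraries, which left closer replicates, gave 829 and 817 for glutamine and 961 and 996 for mutant exudate. Under the other 21 alternatives the counts against WT exudate stayed within 1.5 times: 623 to 950 higher and 709 to 987 lower for glutamine, 712 to 1021 higher and 759 to 1071 lower for mutant exudate, with no change of sign. Genes higher in both numbered 552 to 784 and genes lower in both 584 to 790 (683 and 662 without the highest-scoring libraries). The correlation of the fold changes was 0.886 to 0.951. For mutant exudate minus glutamine, higher genes numbered 10 in the planned fit. They were 24 with the DESeq2 Wald test over 3389 genes, 5 with only the 6 libraries compared and 6 with the replicate block. They were 23 without the highest-scoring and 3 without the lowest-scoring libraries. Leaving out 1 library gave 4 to 14. Lower genes, 4 in the planned fit, were 18, 1, 1, 101 and 0 in the same order (edgeR for the 0; 132 genes had an unadjusted p under 0.05), and 1 to 32 over single libraries. Genes changed 2-fold or more, 7 in the planned fit, were 49 and 3 without the highest-scoring and the lowest-scoring libraries and 4 to 32 over single libraries. Higher genes made up 71.4% of calls, 57.1% with DESeq2, 30.4% without mutant exudate replicate 3 and 18.5% without the highest-scoring libraries; all 14 genes were kept in these 3 fits. The causes were not tested except as given for the within-group axis, and fits with fewer libraries have fewer degrees of freedom. The share of glutamine genes with an interval within 2-fold was 82.8% and 84.5% without the highest-scoring and the lowest-scoring libraries and 84.6% to 91.3% over single libraries. Replicate numbers are shared between groups, but only 2 of 9 same-number correlations of deviations exceeded 0.1 (-0.311 to 0.355). Of the 9 libraries, 2 correlated best with one of their own number (0 in both other groups). No pairing by number was thus seen, though this check cannot exclude libraries prepared in matched batches. With the replicate block 724 and 809 genes were higher and lower for glutamine, and 816 and 882 for mutant exudate. Gene list tests other than tRNA were not run, for lack of names. At this depth and n, simulated 1.5-fold differences were often missed (28.4% recovered in mutant exudate minus WT exudate).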

Other observations

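All tests of the shared response were fixed before their result was seen, except those on rRNA and on the intervals; the tests on the within-group axis and on the 4-tag run were chosen after seeing the data, except the one on WT exudate replicates.

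Genes that differed between mutant exudate and glutamine took several forms when set against WT exudate. The run of 4 tags that holds PFLCHA0_c04080 was low in glutamine alone, and a tag 2 steps before it, chosen after its values were seen, had the same direction but was also lower in mutant exudate than in WT exudate (log2 fold change -0.56, edgeR adjusted p = 0.00706). Other genes were higher in both treatments than in WT exudate, and more so in mutant exudate, among them a pair of neighbouring tags. The 14 calls were not all stable: 5 of the 14 were kept without glutamine replicate 2 or without mutant exudate replicate 1.

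Glutamine and mutant exudate libraries both differed from WT exudate libraries in the same genes. Depth does not account for it: after thinning all libraries to the lowest total, 91.3% of the genes called in the same direction in both comparisons were still called in both. Chance values drawn for each gene on its own do not either, since the covariance of 0.426 lay above the highest of 100 simulations, 0.0332. The simulations held no variation that moves many genes together. They therefore cannot exclude such variation in the shared WT exudate libraries. The rRNA share was at most 0.0318%, but this does not bound the rRNA left, because reads shared by near-identical rRNA copies may have been left out of the counts. A candidate explanation is that glutamine, or an input acting like it, was more available in mutant exudates than in WT exudates. Of the genes that differed 2-fold or more between glutamine and WT exudate, 88.7% had a 95% interval of mutant exudate minus glutamine within 2-fold. The share over all genes tested was 89.8%, so the share by itself does not set these genes apart. The 2 shares are unlike, however. The median absolute log2 fold change between glutamine and WT exudate was 0.309 over all genes tested and 1.35 over these genes. A gene that moved in neither treatment can also have an interval within 2-fold. The same values would follow from something in WT exudates alone, which was not tested.

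The libraries of each group spread along 1 axis in the same genes, with 39.3% of the within-group variance. Scores of replicates 1, 2 and 3 were 11.4, -11.6 and 0.179 in WT exudate, where no single library stood apart. They were 7.71, -2.37 and -5.34 in glutamine, and -11.2, -12.3 and 23.5 in mutant exudate. Mutant exudate replicate 3 had the largest score in size and so weighs most on the axis. The glutamine libraries spread least along it. The tag that varied most within groups had 2371, 2892 and 44754 CPM in mutant exudate replicates 1, 2 and 3. In the same order it had 32309, 2788 and 9215 CPM in WT exudate and 29815, 12446 and 4951 CPM in glutamine. Within groups the score followed the tRNA share (r = 0.895, exact permutation p = 0.00926, adjusted over 3 relations 0.0278; rho = 0.883, p = 0.0324; r = 0.819 without the 2 libraries farthest from the median), which is consistent with a difference in retained short RNA, though a change in the cells could also move both. Library size (r = -0.546, exact permutation p = 0.25, adjusted 0.25; rho = -0.37, p = 0.481; r = -0.27 without 2 libraries) and rRNA share (r = 0.537, p = 0.218, adjusted 0.25; rho = 0.333, p = 0.491; r = 0.571) stay open. The 10 most abundant genes took 15.0% of coding counts in WT exudate replicate 1, 14.5% in glutamine replicate 1 and 16.5% in mutant exudate replicate 3. These are the highest-scoring libraries, and the others had 11.1% to 12.4%. The score and this share come from the same counts, and their relation was not tested. Leaving out the highest-scoring library of each group gained 97 lower genes in mutant exudate minus glutamine. Of these, 92.8% were higher in WT exudate replicate 1 than in replicate 2, against 46.9% of all genes. The axis was computed with these WT exudate libraries and decided which libraries were left out, so the 92.8% is not independent evidence. A remaining difference along the same axis may account for these genes, but this share cannot decide it.

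The run of 4 tags low in glutamine alone does not rest on 1 library, since its median log2 fold change, mutant exudate minus glutamine, was at least 1.87 whichever library was left out. Its median between mutant exudate and WT exudate was 0.28, which is consistent with an input present in both exudates and absent from the glutamine treatment; the run was picked because it showed the pattern, and the composition of the exudates was not measured here.

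With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one put libraries of both treatments on both sides. A treatment difference then added to the spread within sides, so few calls were likely and these splits cannot show what chance gives. The real split called 1721 genes for glutamine minus WT exudate, where the highest other split called 0, 1897 for mutant exudate minus WT exudate, where the highest other called 17, and 14 for mutant exudate minus glutamine, where the highest other called 0; in each case 1 of 10 splits, the real one, gave as many (edgeR).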
